A study of Gallus gallus with 72 samples.

How the data were processed

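RNA from chicken cecal tonsil cells and spleen mononuclear cells was measured on 72 arrays of a 2-colour immune gene microarray. Each array compared cells stimulated with 1 component of Lactobacillus acidophilus with unstimulated cells, labelled in Cy3 and Cy5. The components were DNA, peptidoglycan (PGN) and cell envelope (CE), and cells were taken at 3, 6 and 12 h. The 2 tissues, 3 components and 3 times made 18 groups of 4 arrays, each called a biological replicate by the submitters. In every group replicates 1 and 3 carried the stimulated RNA in Cy3, and replicates 2 and 4 carried it in Cy5.

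The deposited table holds 1 ln ratio of the 2 channels per spot and array. The series text says that the authors normalised the signal globally by LOWESS and used the natural log scale. Image analysis, background correction and the sign of the ratio were not stated. The plan drawn up first had named log2 ratios; the values were used as deposited, in ln. A log10 scale was excluded, because the largest absolute value was 9.347 and 16-bit intensities allow at most 4.816. Natural log and log2 cannot be told apart from the values, so each fold change holds only if the natural log was used.

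The sign was checked in the values. Arrays of different groups correlated at a mean r of 0.0992 over probes where the dyes lay the same way, and at -0.0941 where they lay the opposite way. The dye bias thus changed sign with the labelling, so the ratios were already turned by treatment and no sign was changed. Arrays of the same group with opposite dyes correlated at a mean r of -0.0985, no higher than arrays of different groups. Before removal of the dye bias, most groups thus showed no shared response over all probes. The highest such mean within a group was 0.23, in spleen CE at 6 h. The profile of the dye bias in other groups had the sign of the labelling in 70 of 72 arrays. The exceptions were spleen DNA 3 h replicate 1 (rho 0.0366) and spleen PGN 12 h replicate 3 (rho 0.116). Ratios were read as stimulated over unstimulated; the labels do not state this, and if the reverse holds, every rise is a fall and every count stands.

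The array has 804 spots in 3 identical blocks. The gene annotation gave 1 symbol to 675 spots, several symbols to 3 spots (JAK1 and JAK2) and none to 126. The 675 spots stood for 105 genes, 102 of them with 6 spots each; ACTB had 48, SELE 12 and JAK2 3. Of the 105 genes, 104 were found by identifier in the gene table of the GRCg7b assembly, and BLB1 was not. Spots of 1 gene were averaged on each array. The other 129 spots were tested one by one under their spot numbers; they lie at 21 unlisted layout positions and the JAK1 and JAK2 position. A probe was tested if at least 2 arrays of every group had a value, which kept all 234 probes.

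A linear model was fitted to all 72 arrays with limma 3.58.1 in R 4.3.3. It had 1 coefficient for each of the 18 groups and 1 for the dye orientation of each probe, which left 50 to 53 residual degrees of freedom. Variances were moderated with eBayes. The 39 comparisons were 6 responses averaged over the 3 times, 18 responses at 1 time, 6 changes with time (moderated F test), 6 differences between components within a tissue and 3 differences between tissues. All tests were two-sided. P values were adjusted by Benjamini-Hochberg over the probes of each comparison, and a probe passed at an adjusted p under 0.05. Errors are standard errors of the model, and intervals are 95% intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

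Lists of genes were tested with camera at its preset correlation of 0.01 on the 6 averaged responses, with adjustment over all 60 tests. Camera with an estimated correlation and fry were run beside it. For these tests 46 missing probe means were filled with fitted values. The 10 lists with at least 4 measured genes were proinflammatory cytokines, chemokines, chemokine receptors, cytokine receptors, JAK-STAT signalling, Toll-like receptor and NF-kappaB signalling, T cell markers, MHC and antigen presentation, apoptosis, and adhesion and integrins. Lists with too few measured genes were not tested: T cell and regulatory cytokines (3 measured), B cell markers (2), housekeeping genes (2), MAP kinase and AP-1 (1), macrophage and granulocyte markers (1), natural killer and cytotoxic cell markers (1), cell cycle and proliferation (1), interferon response (0), and red cell, platelet and epithelial markers (0).

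The lists, the comparisons, the tests and the rule for named genes were set before the data were examined. For each averaged response the rule takes up to 12 probes with the largest rise and 12 with the largest fall among those that passed, and the 5 with the smallest p where fewer than 5 passed. At each time it takes up to 5 rises and 5 falls, and for differences up to 5 with the smallest p. From each tested list it allows up to 4 members per averaged response, of which only some are printed. Genes that passed at 1 time or changed with time and lie outside the rule were chosen after their values were seen: BLB1, BF2, TAP2, K123, RWDD4, TLR3 and NFKB1 in spleen PGN at 12 h; STAT4, LOC395551, K123, NFKB1, CD164, AKT1, CISH, SH2D6 and MYC in spleen CE at 6 h; CD74 in the change with time of spleen PGN; and NFKB1, K123 and MYC in that of spleen CE. Ratios of single arrays were also picked after they were seen.

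Alternatives set in advance were no dye coefficient, 1 fit per tissue, a replicate block in place of the dye coefficient, a random block of tissue, time and replicate number, arrays centred on the median, arrays centred and scaled, only probes with a value on all 72 arrays, array weights, no averaging of spots, every sign turned, an unmoderated fit per tissue with unadjusted or adjusted p, and each array left out in turn. Chosen after seeing the data were the median over spots, the repeated value of an array set to missing, unnamed spots averaged by layout position, named genes only, no arrays with missing spots, 5 doubted arrays left out, spleen PGN 6 h replicate 2 with its sign turned, and each array left out in turn for the layout positions that passed. Under the alternatives the lists were tested with cameraPR on the moderated statistic.

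The number of arrays limits the precision. The median standard error was 0.14 for an averaged response, 0.25 at 1 time and 0.20 for a difference. Over arrays, the median r between adjacent spots of a pair was 0.217, that between the first 2 blocks was 0.158, and the median SD of the 48 ACTB spots was 0.144. The dye coefficient passed at 82 probes. The procedure was tested on simulated data in 20 runs, with 30 of 234 probes changed. The simulated noise was normal with the residual SD of each probe, independent between probes, and held no outlying arrays. The changes were ln ratios of 0.5, 1 and 2, up or down. In spleen CE at 6 h the procedure found 18% of changes of 0.5, 50% of 1 and 91% of 2. False calls had a mean of 0.7 per run. For the averaged response the procedure found 56.5%, 85% and 98.5%, with 0.95 false calls. A list raised by 0.5 in ln ratio was called in 20 of 20 runs, and 0 of 180 other lists were called by camera. The real data hold outlying arrays and related spots, so these rates need not hold for them.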

Results

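Ratios of stimulated to unstimulated cells were measured on 72 arrays, 4 for each of 18 groups of tissue, bacterial component and time. Cecal tonsils are lymphoid tissue of the gut wall, and the spleen filters the blood. Peptidoglycan (PGN) is the sugar and peptide mesh of the bacterial wall, and the cell envelope (CE) fraction holds the wall with its attached layers. The array covers 105 named genes, mostly of the immune system, in 6 spots each for 102 of them. Of the 804 spots, over 10% had no value on 3 arrays, and at most 2 spots lacked one on any other. Of the 3, cecal tonsil CE 3 h replicate 4 had 477, spleen DNA 3 h replicate 3 had 543 and cecal tonsil CE 12 h replicate 4 had 710. Array medians lay between -0.06 and 0.08. On 1 array, spleen DNA 6 h replicate 2, the control channel was labelled as cecal tonsil, and the stimulated sample of spleen CE 12 h replicate 1 was labelled "cecal Spleen". Both were kept in the groups of their titles. Values are ln ratios read as stimulated over unstimulated, with the standard error and the number of arrays. Neither the sign nor the natural log could be settled from the values, so each fold and direction rests on that reading.

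**Figure D1:**
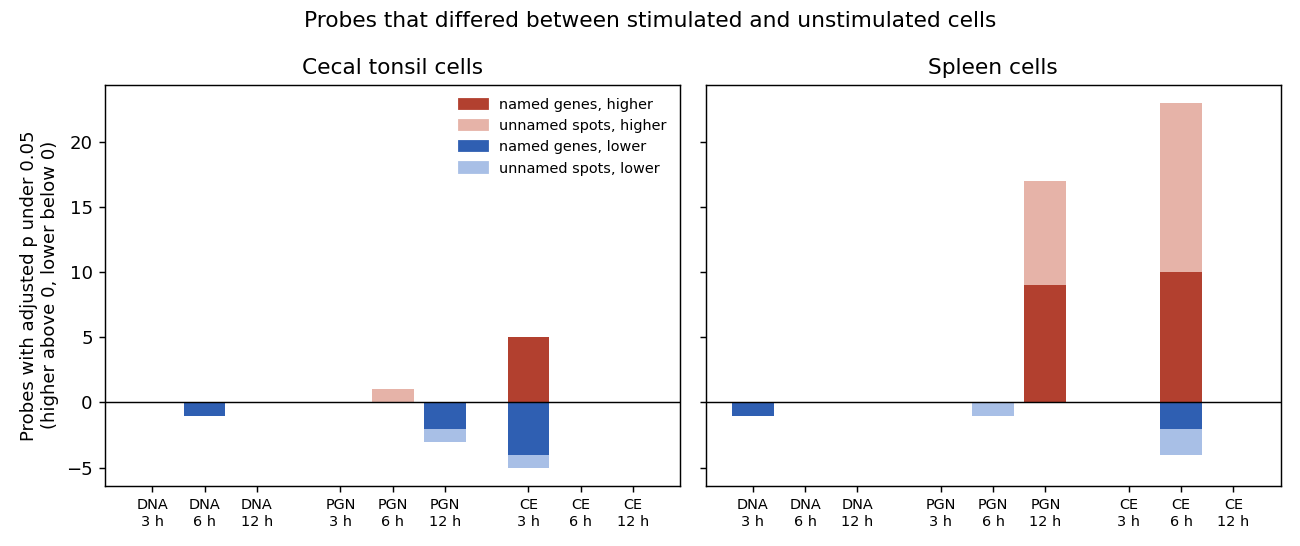
Probes with an adjusted p under 0.05 in each of the 18 groups (x axis: component and time, y axis: number of probes, higher above 0 and lower below 0), split into named genes and unnamed spots. The longest bars are spleen CE at 6 h, with 23 higher and 4 lower, and spleen PGN at 12 h, with 17 higher and 0 lower.

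Spleen cells answered the cell envelope at 6 h. LY6E, a surface protein of lymphocytes that interferon induces, rose 12.4-fold (ln ratio 2.51 ± 0.42, n = 4, higher in 4 of 4 arrays, adjusted p = 1.43e-05). STAT4, the transcription factor that carries interleukin-12 signals, rose 5.92-fold (1.78 ± 0.30, n = 4, 4 of 4, adjusted p = 1.43e-05). NFKB1, a subunit of the transcription factor NF-kappaB, rose 2.07-fold (0.73 ± 0.18, 4 of 4, adjusted p = 0.00306). LOC395551 rose 4.95-fold (1.60 ± 0.36, 4 of 4, adjusted p = 0.00104) and K123 rose 3.13-fold (1.14 ± 0.28, 4 of 4, adjusted p = 0.0025). These 5 genes passed with any 1 array left out. On the GRCg7b assembly LY6E lies on chromosome 2 (147255592 to 147261662), STAT4 on chromosome 7 (7538207 to 7577113) and NFKB1 on chromosome 4 (60304611 to 60362176). LOC395551 lies on chromosome 19 (906402 to 907528) and K123 on chromosome 1 (4008646 to 4020411). Also higher were CD164, a sialomucin of the cell surface (1.56-fold, adjusted p = 0.00787), the kinase AKT1 (2.05-fold, 0.015), the cytokine signal inhibitor CISH (2.12-fold, 0.0371) and SH2D6 (1.80-fold, 0.0458), each higher in 4 of 4 arrays. The growth regulator MYC rose 2.11-fold (3 of 4 arrays, 0.049). CD8BP, an annotated CD8 beta chain gene of T cells, fell 1.76-fold (-0.57 ± 0.16, lower in 4 of 4, 0.0132). PCK1, an enzyme of glucose synthesis, fell 2.49-fold (-0.91 ± 0.29, 4 of 4, 0.0292). In all, 27 of 234 probes passed at 6 h, 23 higher and 4 lower, and 12 of them were named genes. The other 15 were unnamed spots of 5 layout positions, counted singly. Between 21 and 26 passed with 1 array left out. Without replicate 1, CD8BP was at -0.39 (adjusted p = 0.292), PCK1 at -0.61 (0.432), AKT1 at 0.47 (0.384) and CISH at 0.50 (0.51). Without replicate 3, CD8BP (0.111), CISH (0.113), SH2D6 (0.187), MYC (0.405) and CD164 (0.0586) missed the threshold. The threshold was also missed by MYC (0.116) and SH2D6 (0.184) without replicate 2 and by SH2D6 without replicate 1 (0.138). Without replicate 4 it was missed by MYC (0.136), PCK1 (0.0615) and CD164 (0.0556).

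At 3 h and at 12 h, 0 probes passed for the cell envelope in spleen cells with limma or with an unmoderated fit, and 14 and 15 had an unadjusted p under 0.05. Without 12 h replicate 1 or 4, 1 passed at 12 h. The response changed with time at 15 probes, of which 10 were unnamed spots of 5 layout positions. LY6E was at -0.25, 2.51 and -0.47 at 3, 6 and 12 h (adjusted p = 0.000871), and STAT4 at 0.09, 1.78 and -0.16 (0.00254), over 4 arrays per time. NFKB1 was at 0.09, 0.73 and -0.30 (0.024), K123 at 0.67, 1.14 and -0.34 (0.0325) and MYC at -0.09, 0.75 and -0.64 (0.0325). The mean at 12 h hid a split: STAT4 was at 1.18 and 1.37 in replicates 1 and 2 and at -1.66 and -1.54 in replicates 3 and 4. LY6E was at 0.50 and 0.48 against -1.34 and -1.52. Averaged over the 3 times, LOC395551 rose 2.12-fold (0.75 ± 0.21, n = 12, higher in 11 of 12 arrays, adjusted p = 0.0419). CD8BP fell 1.44-fold (-0.36 ± 0.09, lower in 10 of 12, 0.026). In all, 6 probes passed in this average, 5 higher and 1 lower, with 4 unnamed spots of 2 layout positions among them. STAT4 did not pass in it (0.57 ± 0.17, higher in 8 of 12, 0.0517). The change of LY6E and STAT4 passed with any 1 array left out. The number of changing probes was 5 without 6 h replicate 2, 4 without 6 h replicate 3, 5 without 6 h replicate 4 and 6 without 12 h replicate 3. Without any 1 of these or 12 h replicate 4 the changes of NFKB1, K123 and MYC missed the threshold. The number in the average was 14 without 12 h replicate 3 or replicate 4 and 3 without 3 h replicate 1, 3 h replicate 4 or 6 h replicate 2. It was 2 without 3 h replicate 2 or 3, 1 without 6 h replicate 3 or 12 h replicate 1, and 0 without 12 h replicate 2. LOC395551 missed the threshold without any 1 of 7 of the 12 arrays and CD8BP without any 1 of 6. With 1 limma fit per tissue 0 probes passed in the average and 1 in the change with time.

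**Figure D2:**
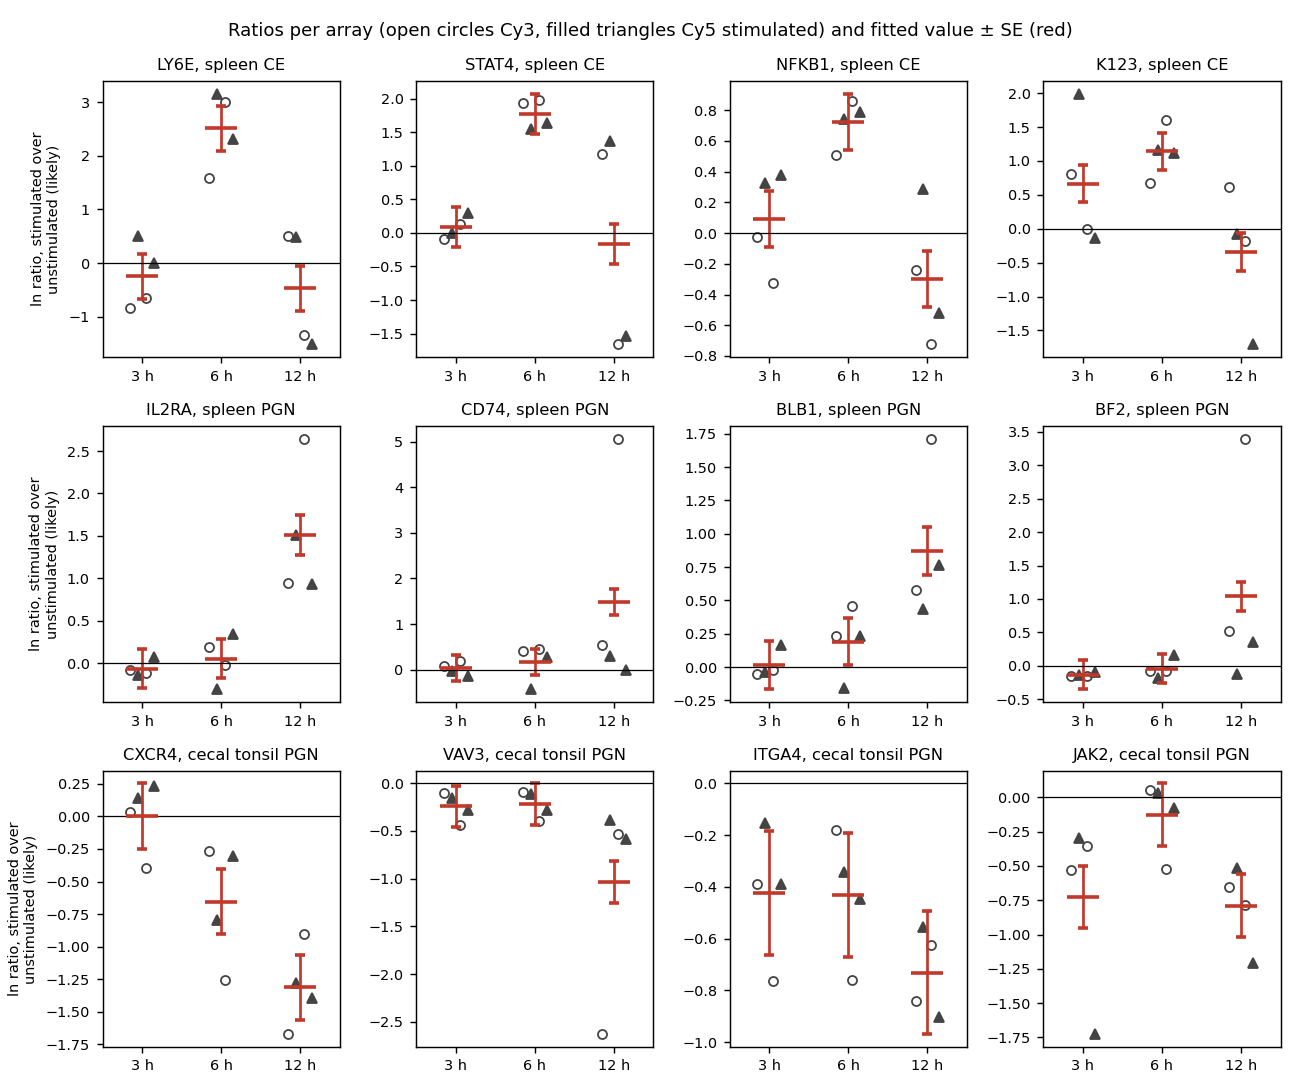
ln ratios of 12 gene and component pairs at 3, 6 and 12 h (x axis: time, y axis: ln ratio), 1 symbol per array, open circles with the stimulated RNA in Cy3 and filled triangles in Cy5, with the fitted value and its standard error in red. STAT4 with the cell envelope lies between 1.55 and 1.98 on the 4 spleen arrays at 6 h, and CD74 with PGN at 12 h is at 5.07 on replicate 3 and at 0.53 or below on the other arrays.

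Spleen cells answered PGN at 12 h. IL2RA, the alpha chain of the interleukin-2 receptor, which activated T cells display, rose 4.53-fold (1.51 ± 0.23, n = 4, higher in 4 of 4 arrays, adjusted p = 4.38e-06). K123, whose gene lies next to IL2RA (4023671 to 4042984) on chromosome 1, rose 3.52-fold (1.26 ± 0.28, 4 of 4, 0.000818), with single arrays between 1.10 and 1.43. Of the list of MHC and antigen presentation 4 genes also passed, but not without replicate 3. BLB1, an MHC class II beta chain, rose 2.39-fold (0.87 ± 0.18, 4 of 4, 0.000478), and CD74, the invariant chain that guides class II molecules, rose 4.37-fold (1.47 ± 0.29, 3 of 4, 0.000291). BF2, an MHC class I molecule, rose 2.84-fold (1.04 ± 0.22, 3 of 4, 0.000478), and TAP2, a subunit of the peptide transporter, 2.85-fold (1.05 ± 0.25, 3 of 4, 0.00241). NFKB1 rose 1.88-fold (0.63 ± 0.18, 4 of 4, 0.0136). TLR3, a receptor for double-stranded RNA, rose 2.27-fold (0.82 ± 0.23, 3 of 4, 0.00945) and RWDD4 rose 2.96-fold (1.08 ± 0.27, 3 of 4, 0.00349). In all, 17 probes passed, each of them higher, of which 8 were unnamed spots of 3 layout positions and 9 were named genes. Of these 9, K123 and NFKB1 were also among the 12 that passed with the cell envelope at 6 h, where 1.03 shared genes would be met by chance. Replicate 3 had the highest ratio of CD74 (5.07), BF2 (3.40) and TAP2 (3.61). There the housekeeping gene ACTB was at 2.46 too, against -0.27 to -0.21 on the other 3 arrays. Without it 3 probes passed, IL2RA at 1.07 (0.00949), K123 at 1.30 (0.0216) and NFKB1 at 0.79 (0.0252). BLB1 was then at 0.55 (0.106), CD74 at 0.33 (0.161), BF2 at 0.26 (0.329), TAP2 at 0.20 (0.672), TLR3 at 0.04 (0.959) and RWDD4 at 0.02 (0.968). Without replicate 2, NFKB1 was at 0.45 (0.193), and without replicate 4, 28 probes passed.

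At 3 h, 0 probes passed with PGN in spleen cells with limma or with an unmoderated fit, and 5 had an unadjusted p under 0.05. At 6 h, 1 unnamed spot passed (spot_231, -1.66 ± 0.40, n = 4), which stood at -6.50 on replicate 1 and missed the threshold without it. Without replicate 2, 10 probes passed. STAT4 at 6 h was at 1.48, 1.43 and 1.09 on replicates 1, 3 and 4 and at -1.54 on replicate 2, and did not pass (0.61 ± 0.30, adjusted p = 0.984). The response changed with time at 6 probes, of which 3 were unnamed spots of 1 layout position. The named genes were IL2RA (-0.06, 0.05 and 1.51 at 3, 6 and 12 h, n = 4 each, adjusted p = 0.00202), BF2 (-0.13, -0.04 and 1.04, 0.0244) and CD74 (0.03, 0.18 and 1.47, 0.0408). Averaged over the times, 12 probes passed, each of them higher, and 5 were unnamed spots of 1 layout position. The 7 named genes were STAT4 (0.57 ± 0.17, n = 12, 11 of 12 arrays, adjusted p = 0.0429), CD74 (0.56 ± 0.16, 8 of 12, 0.0369), K123 (0.52 ± 0.16, 8 of 12, 0.0429), IL2RA (0.50 ± 0.13, 7 of 12, 0.0235), MYC (0.48 ± 0.15, 11 of 12, 0.0429), NFKB1 (0.38 ± 0.11, 11 of 12, 0.0264) and BLB1 (0.36 ± 0.10, 8 of 12, 0.0349), which are rises of 1.43-fold to 1.76-fold. Of the 12 arrays, leaving out any 1 of 6 to 10 of them ended the call, 6 for IL2RA and NFKB1 and 10 for STAT4. The number of changing probes was 0 without 12 h replicate 3, 10 without 6 h replicate 3 or 12 h replicate 2 and 11 without 12 h replicate 4. The number in the average was 0 without 6 h replicate 1, 3 or 4, 1 without 12 h replicate 3, 3 without 3 h replicate 1 or 3 and 6 without 3 h replicate 4. With 1 limma fit per tissue 0 probes passed in the average and in the change with time.

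In cecal tonsil cells with PGN, CXCR4, VAV3, ITGA4 and JAK2 fell. CXCR4, the receptor that draws lymphocytes towards CXCL12, fell 3.71-fold at 12 h (-1.31 ± 0.25, n = 4, lower in 4 of 4 arrays, adjusted p = 0.000623). Averaged over the times it fell 1.92-fold (-0.65 ± 0.15, n = 12, lower in 9 of 12, 0.00769). Both falls passed with any 1 array left out. VAV3, an activator of small GTPases that shape the cytoskeleton, fell 1.65-fold in the average (-0.50 ± 0.12, lower in 12 of 12, 0.0148) and 2.82-fold at 12 h (-1.04 ± 0.22, 4 of 4, 0.0014). ITGA4, the alpha 4 integrin that binds VCAM1, fell 1.70-fold in the average (-0.53 ± 0.14, lower in 12 of 12, 0.0183). The cytokine receptor kinase JAK2 fell 1.73-fold (-0.55 ± 0.13, lower in 10 of 12, 0.0128). CXCR4 lies on chromosome 7 (30380917 to 30383608), as does ITGA4 (13932489 to 13966234), VAV3 on chromosome 8 (1002266 to 1150420) and JAK2 on chromosome Z (27948291 to 28033831). In all, 5 probes passed in the average, 4 of these named genes and a spot annotated to both JAK1 and JAK2, and 0 were higher. CD3D and CD5, markers of T cells, were above 0 in 12 of 12 arrays (0.42 ± 0.17 and 0.34 ± 0.16) and did not pass (0.329 and 0.442). The other measured T cell markers were mixed at 12 h. ZAP70 (-0.38), CD28 (-0.24) and IL2RA (-0.23) lay below 0, and CD8A (0.26), CD4 (0.12) and GATA3 (0.01) above. At 3 h, 0 probes passed with limma or with an unmoderated fit, and 9 had an unadjusted p under 0.05. At 6 h, 1 unnamed spot passed (spot_381, 2.75 ± 0.67, 4 of 4, 0.0288) and missed the threshold without replicate 1, 2 or 3. At 12 h, 3 passed. With limma 0 probes changed with time, 8 had an unadjusted p under 0.05, and 2 passed in an unmoderated fit. Without 6 h replicate 4, 1 passed with limma. Without 12 h replicate 1, where VAV3 was at -2.63, VAV3 was at -0.53 at 12 h (0.269) and at -0.33 in the average (0.138). The number in the average was 1 without 3 h replicate 4, 2 without 6 h replicate 4 or 12 h replicate 4, and 3 without 3 h replicate 3 or 6 h replicate 3. ITGA4 missed the threshold without any 1 of these 5. JAK2 did without 3 h replicate 4 (0.109) or 12 h replicate 4 (0.0591) and VAV3 without 3 h replicate 4 (0.0656) or 6 h replicate 4 (0.0507).

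With the cell envelope in cecal tonsil cells at 3 h, 10 probes passed, 5 higher and 5 lower. VCAM1, an adhesion molecule for white blood cells, stood 5.97-fold higher (1.79 ± 0.37, n = 4, 3 of 4 arrays, adjusted p = 0.00235). KIT, the stem cell factor receptor, stood 8.43-fold higher (2.13 ± 0.47, 4 of 4, 0.0042) and the chemokine XCL1 5.78-fold (1.75 ± 0.42, 4 of 4, 0.00821), beside growth hormone (GH) and LY6E. Lower were ZAP70, the T cell receptor kinase (-0.82 ± 0.22, n = 3, 3 of 3, 0.0254), IFNAR1, a chain of the type I interferon receptor (-0.54 ± 0.16, n = 4, 4 of 4, 0.0397), LFNG and TOB1. Replicate 4, the array with 477 measured spots, had ratios of 4.68 for VCAM1, 5.44 for KIT, 5.72 for XCL1, 6.29 for GH, 5.03 for LY6E, -3.49 for LFNG and -5.89 for TOB1. Without it 0 probes passed: VCAM1 was at 0.79 (0.73), KIT at 0.96 (0.841), XCL1 at 0.43 (0.998), ZAP70 at -0.82 (0.125) and IFNAR1 at -0.54 (0.508). With limma 0 probes passed at 6 h, at 12 h, in the average and in the change with time, and 9, 15, 19 and 21 had an unadjusted p under 0.05. An unmoderated fit gave 0, 0, 1 and 0. Nearest in the average were ZAP70 (-0.38 ± 0.12, n = 11, lower in 8 of 11, 0.147), JAK2 (-0.41 ± 0.13, n = 12, lower in 8 of 12, 0.156) and VCAM1 (0.61 ± 0.21, n = 12, higher in 9 of 12, 0.275). With 1 array left out, 3 passed at 6 h without replicate 1 or 3, 4 at 12 h without replicate 1 and 1 without replicate 4. In the average 2 passed without 3 h replicate 2 and 1 without 12 h replicate 1. In the change with time 1, 6 and 4 passed without 3 h replicate 1, 2 and 3, and 3 without 12 h replicate 3.

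Few genes passed with bacterial DNA. In cecal tonsil cells IL3, a growth factor of blood cells, fell 2.11-fold at 6 h (-0.75 ± 0.17, n = 4, lower in 3 of 4 arrays, adjusted p = 0.00811), with ratios of 0.00, 0.02, -1.77 and -1.24. IL3 missed the threshold without replicate 3 (-0.44, 0.674) or replicate 4 (-0.54, 0.296), and 3 probes passed without replicate 2. The gene of interferon gamma (IFNG), the main activator of macrophages, was 2.12-fold higher in the average (0.75 ± 0.27, n = 12, 9 of 12 arrays) and did not pass (0.378). TNFRSF8, a receptor of activated lymphocytes, was at 0.32 ± 0.10 (9 of 12, 0.247) and the chemokine receptor CCR8 at 0.46 ± 0.18 (9 of 12, 0.385). TLR7, a receptor for single-stranded RNA, was at -0.30 ± 0.12 (lower in 9 of 12, 0.385) and the inflammatory cytokine IL6 at -0.24 ± 0.11 (lower in 10 of 12, 0.51). With limma 0 probes passed at 3 h, at 12 h, in the average and in the change with time, with 17, 13, 17 and 15 at an unadjusted p under 0.05. An unmoderated fit gave 0 in each. With 1 array left out, 1 passed in the average without 6 h replicate 1, 6 h replicate 2 or 12 h replicate 2, and 1 at 12 h without replicate 2. In the change with time 2 passed without 6 h replicate 3 and 1 without 3 h replicate 1, 6 h replicate 1, 2 or 4, or 12 h replicate 1. With arrays centred and scaled, 51 probes passed at 3 h, 3 in the average and 14 in the change with time, and IL3 did not pass at 6 h (0.198).

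In spleen cells with DNA, TLR4, the receptor for lipopolysaccharide, stood 6.00-fold lower at 3 h (-1.79 ± 0.45, n = 4, lower in 2 of 4 arrays, adjusted p = 0.0443). This rested on -6.54 on replicate 3, the array with 543 measured spots. Without it TLR4 was at -0.17 (0.996) and 0 probes passed. Without replicate 1, 2 or 4, 2 probes passed. VAV3 was at -0.31 ± 0.12 in the average (lower in 10 of 12) and PTPRC, the CD45 phosphatase of white blood cells, at -0.23 ± 0.10 (lower in 8 of 12). CD40, a costimulatory receptor of B cells and macrophages, was at 0.41 ± 0.18 (higher in 6 of 12). Each of the 3 had an adjusted p of 0.937. With limma 0 probes passed at 6 h, at 12 h, in the average and in the change with time, with 3, 19, 6 and 13 at an unadjusted p under 0.05. An unmoderated fit gave 0 in each, and in the change with time 1 passed without 3 h replicate 2 or 4. With no averaging of spots, 7 spots passed at 12 h and 0 at 3 h.

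Of the 60 tests of gene lists on the averaged responses, 1 passed. The 8 measured genes of MHC and antigen presentation lay above 0 in spleen cells with PGN, 8 of 8, with a mean of 0.28 (camera adjusted p = 0.01, adjusted p = 0.359 with an estimated correlation, fry adjusted p = 0.00972). Of the 8, BLB1 and CD74 rose, and 4 passed when adjusted over the list alone, with TAP2 (0.41 ± 0.14, n = 12, 7 of 12 arrays, adjusted p over all probes 0.1) and BF2 (0.29 ± 0.13, above 0 in 4 of 12, 0.243). The list missed the threshold without 12 h replicate 3, where ACTB was at 2.46 (cameraPR adjusted p = 0.122), and without 6 h replicate 2 (0.0575). The 6 cytokine receptors lay below 0 in cecal tonsil cells with PGN, 6 of 6, and passed with fry (adjusted p = 0.0429) but not with camera (0.235, adjusted p = 0.564 with an estimated correlation). IFNAR2 (-0.41 ± 0.13, n = 12, lower in 11 of 12, 0.0626) and IFNAR1 (-0.26 ± 0.09, lower in 9 of 12, 0.205), the chains of the type I interferon receptor, passed when adjusted over the list alone.

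The other tested lists passed in no averaged response with camera or fry. Their smallest camera adjusted p were 0.332 for chemokines (4 genes, cecal tonsil CE), 0.644 for JAK-STAT signalling (4 genes, cecal tonsil CE) and 0.644 for T cell markers (8 genes, spleen DNA). They were 0.802 for proinflammatory cytokines (6 genes), 0.802 for Toll-like receptor and NF-kappaB signalling (6 genes), 0.802 for apoptosis (10 genes), 0.802 for adhesion and integrins (5 genes) and 0.818 for chemokine receptors (4 genes). Adjusted over the list alone, CXCR4 among chemokine receptors, JAK2 in JAK-STAT signalling and ITGA4 among integrins passed with PGN in cecal tonsil cells. There JAK2, ZAP70 among T cell markers and VCAM1 among adhesion molecules passed with the cell envelope. Part of that VCAM1 average came from 3 h replicate 4, without which its 3 h value went from 1.79 to 0.79. In spleen cells STAT4 in JAK-STAT signalling passed with PGN and with the cell envelope. With PGN in spleen cells IL2RA among cytokine receptors and among T cell markers, NFKB1, and the adhesion receptor CD44 (0.24 ± 0.09, n = 12, 9 of 12, 0.139 over all probes) passed too. In proinflammatory cytokines, chemokines and apoptosis 0 members passed in this way in the averaged responses.

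No difference between components passed in either tissue. With limma 0 probes passed in each of the 6 pairs, with 21, 9 and 12 at an unadjusted p under 0.05 in cecal tonsil cells (PGN minus DNA, CE minus DNA, CE minus PGN) and 13, 21 and 9 in spleen cells. An unmoderated fit gave 2, 0 and 2, and 0, 0 and 0. CXCR4 was nearest in the cecal tonsil, lower with PGN than with DNA by -0.76 (95% interval -1.17 to -0.35, adjusted p = 0.119). It was higher with the cell envelope than with PGN by 0.70 (0.29 to 1.11, 0.25), over 12 arrays each. In spleen cells STAT4 differed by 0.00 between the cell envelope and PGN (-0.49 to 0.49, 0.999), LOC395551 by 0.55 (-0.04 to 1.15, 0.82) and IL2RA by -0.33 (-0.71 to 0.05, 0.82), so that differences of about those sizes were not excluded. CD74 was higher with PGN than with DNA by 0.62 (0.16 to 1.09, 0.499). Without spleen PGN 6 h replicate 2, 8 probes passed for PGN minus DNA, and 1 passed without spleen DNA 3 h replicate 2. For CE minus DNA 1 passed in the spleen without CE 3 h replicate 2 or 12 h replicate 3 or 4, and in the cecal tonsil without DNA 12 h replicate 2.

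For PGN some probes passed as different in response between the 2 tissues, though splits of the arrays did not exclude chance. STAT4 was lower in cecal tonsil cells, at -0.08, -0.19 and -0.67 at 3, 6 and 12 h, than in spleen cells, at 0.20, 0.61 and 0.89, a difference of -0.88 ± 0.24 (95% interval -1.37 to -0.39, 12 arrays per tissue, adjusted p = 0.0303) or 2.41-fold. In all, 6 of 234 probes passed, STAT4 and 5 unnamed spots of 1 layout position, each lower in the cecal tonsil. IL2RA (-0.58 ± 0.19) and CXCR4 (-0.64 ± 0.20) did not pass (0.0695 each). For DNA and the cell envelope 0 probes differed between tissues with limma, with 14 and 29 at an unadjusted p under 0.05. Without spleen CE 12 h replicate 4, 1 differed for the cell envelope. For PGN 3 probes passed without cecal tonsil 3 h replicate 3, 6 h replicate 2 or 3, or 12 h replicate 1, and without spleen 3 h replicate 3, 6 h replicate 3 or 4, or 12 h replicate 1. The number was 12 without spleen 6 h replicate 2 and 11 without spleen 12 h replicate 4. STAT4 missed the threshold without any 1 of 13 of the 24 arrays, at an adjusted p of at most 0.0945. With arrays centred and scaled 0 probes differed for PGN, with STAT4 at -0.67 (0.139), and with named genes only 0 differed (0.0565).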

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

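Of the tests in this part, the splits of arrays and the share of high spots were planned, and the other 7 were chosen only after the result was seen. In cecal tonsil CE at 3 h, 9 named genes passed, among them VCAM1, KIT, XCL1 and ZAP70, and replicate 4 had 477 of 804 spots. Of the 9 genes, 4 had every measured replicate on the side of their mean, below the bound set for a like response of the 4 cultures. The genes were taken because they passed, and the count was set against no spread, so it does not decide the question. Replicate 4 carried the values of 7 of the 8 genes measured on it, which lost over 50% of their ln ratio without it. Whether its missing spots are the cause stays open. That replicate 4 carries the value is argued against for IFNAR1, which was at -0.54 with and without that array and then missed the threshold (0.508). ZAP70 had no value there. Whether the culture of that array responded differently was not tested.

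Spleen PGN 12 h replicate 3 had the highest ratios of the antigen presentation genes CD74 (5.07), BF2 (3.40), TAP2 (3.61) and BLB1 (1.71), 239 of its spots stood at 1 repeated value, and the housekeeping gene ACTB was at 2.46 (SD 2.23 over 48 spots), against -0.27 to -0.21 on the other 3 arrays. This array carried the values of CD74, BF2 and TAP2, which lost over 50% of their ln ratio without it, while BLB1 kept 0.55 of 0.87. A control signal at its floor would put high ratios above 0, and 70.7% of the 157 spots beyond an absolute ln ratio of 2 lay there, between the bounds set for and against it. That its ratio was turned over is undecided too: its dye profile lay opposite to its labelling (rho 0.116), but of the 3 genes that passed without it IL2RA (2.65) and K123 (1.29) lay on the same side on it by more than their standard error and NFKB1 (0.04) did not. A stronger response of that culture was not tested.

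Spleen PGN 6 h replicate 2 lay opposite to its group, with STAT4 at -1.54 against 1.48, 1.43 and 1.09 and LY6E at -1.04 against 1.20, 0.67 and 1.96. A ratio formed the wrong way round is argued against, because it would turn the dye bias over too, and the array followed the dye profile of other groups on its labelled side (rho 0.253). An exchange of stimulated and control RNA, in the tubes or in the channel labels, would leave the dye bias in place and stays open as a candidate explanation. With the dye removed, its r over probes with the mean of the other 3 arrays was -0.498, the lowest of 72, and the next was -0.336 (spleen DNA 6 h replicate 1). An opposite response of that culture would give the same values and was not tested.

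By Dixon's test at the 95% level, which chance meets in about 1 in 20 groups, 1 array lay apart from the other 3 in 2 of 18 groups by its spots at a repeated value and in 0 of 18 by the SD of its ratios. The number of measured spots met it in 8 of the 14 groups where it differed, but near the ceiling of 804 a loss of 1 or 2 spots is enough, so that share does not apply. Measured spots numbered 477 on cecal tonsil CE 3 h replicate 4, 710 on cecal tonsil CE 12 h replicate 4 and 543 on spleen DNA 3 h replicate 3. Of 804 spots, 802 were measured on cecal tonsil DNA 6 h replicate 1, DNA 12 h replicate 2 and PGN 6 h replicate 1, and 803 on cecal tonsil PGN 12 h replicate 4 and spleen DNA 6 h replicate 3. In the groups that met it by a repeated value, that value stood at 239 spots on spleen PGN 12 h replicate 3 and at 131 on spleen CE 6 h replicate 1. Repeated values were common, at over 7 spots on 69 of 72 arrays. They stood at 349 spots on cecal tonsil DNA 3 h replicate 4 and at 244 on spleen CE 3 h replicate 3.

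The same test picked out 10 of 33 pairs of a named gene that passed and its group. The pairs were taken because they passed and several share 1 array, so the share of 1 in 20 does not apply to them. On cecal tonsil CE 3 h replicate 4 the ln ratio was -3.49 for LFNG, -5.89 for TOB1, 6.29 for GH and 5.03 for LY6E. On spleen PGN 12 h replicate 3 it was 4.30 for RWDD4, 5.07 for CD74 and 3.21 for TLR3. On spleen CE 6 h replicate 1 it was 1.65 for AKT1 and -0.12 for MYC, and on cecal tonsil PGN 12 h replicate 1 it was -2.63 for VAV3.

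Groups differed under 3 tests of a difference. The response of spleen cells changed with time at 6 probes for PGN and at 15 for CE, and the tissues differed in their response to PGN at 6 probes. In splits that drew the time labels anew within spleen cells, 8 of 100 gave at least 6 for PGN (highest other 12) and 6 of 100 gave at least 15 for CE (highest other 18), so chance was not excluded. For the tissues and PGN 2 of 100 splits gave at least 6, a share under 0.05, though the highest other gave 9. Splits were made for each of the 39 comparisons, where some shares under 0.05 are met by chance, so chance was not excluded here either.

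For the averaged responses, splits exchanged the samples of drawn arrays together with their dyes. For cecal tonsil PGN 1 of 100 splits, the real one, gave 5 and the highest other gave 1. That share is under 0.05, but over the 39 comparisons some such shares are met by chance. Chance was thus not excluded here either. Chance was not excluded for spleen PGN (12, with 6 of 100 splits as high and 18 as the highest other) or spleen CE (6, with 10 of 100 and 25). The 25 is several times the real number and points to a structure of the spleen CE arrays. Their 12 h replicates 3 and 4 lay opposite to replicates 1 and 2, but which arrays that split exchanged was not recorded. Where 0 probes had passed, each of the 100 splits gave as many, and the highest other was 1 for cecal tonsil DNA, 2 for cecal tonsil CE and 2 for spleen DNA. In the change with time it was 2, 0 and 4 for DNA, PGN and CE in cecal tonsil cells and 3 for DNA in spleen cells. Between components it was 1 for each of the 3 pairs in cecal tonsil cells, and 7, 1 and 10 in spleen cells for PGN minus DNA, CE minus DNA and CE minus PGN. Between tissues it was 1 for DNA and 10 for CE.

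At 1 time, 8 splits of 4 arrays are too few for a share under 0.05. The real number and the highest other at 3, 6 and 12 h were 0 and 1, 1 and 2, and 0 and 1 for DNA in cecal tonsil cells. They were 0 and 0, 1 and 1, and 3 and 4 for PGN there, and 10 and 9, 0 and 0, and 0 and 2 for CE. In spleen cells they were 1 and 3, 0 and 2, and 0 and 1 for DNA, 0 and 0, 1 and 15, and 17 and 16 for PGN, and 0 and 0, 27 and 11, and 0 and 23 for CE. The 15 came with PGN 6 h replicate 2 exchanged and the 23 with CE 12 h replicates 3 and 4 exchanged. Against real numbers of 1 and 0, both point to a structure of the samples, in which those arrays lie opposite to the others of their group. The 16 came with PGN 12 h replicate 3 exchanged.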

How the results depend on the processing

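Chosen only after the data were seen were the alternatives from the median over spots to spleen PGN 6 h replicate 2 turned, and the others were planned. In spleen CE at 6 h, 5 genes passed under each alternative that gave them a value, left-out arrays included, as did IL2RA in spleen PGN at 12 h and CXCR4 in cecal tonsil PGN at 12 h and in the average. The ranges and largest adjusted p that follow are over the alternatives with no array left out in turn. LY6E ranged from 2.14 to 2.67, STAT4 from 1.46 to 1.78, LOC395551 from 1.35 to 1.65, K123 from 0.96 to 1.52 and NFKB1 from 0.61 to 0.73, at an adjusted p of at most 0.0286. IL2RA in spleen PGN at 12 h ranged from 0.90 to 2.17 (at most 0.00895). CXCR4 in cecal tonsil PGN ranged from -1.37 to -0.81 at 12 h (at most 0.00546) and from -0.69 to -0.51 in the average (at most 0.0268), and in the average JAK2 and ITGA4 passed under each of these (at most 0.0332 and 0.0302), though not with every array left out. Over the 89 gene and comparison pairs that passed, 1156 of 1445 values kept side and direction, 287 missed the threshold and 2 reversed. Of the 27 pairs given that had not passed, 390 of 443 values stayed so and 53 passed. With every sign turned each count stood, which was fixed in advance, because turning all signs changes no p value. The lists passed in 0 tests with an estimated correlation and in 2 with fry, against 1 with camera. Differences between tissues have no value in the fits per tissue, and lists have none with no averaging of spots. No signal intensities or backgrounds were used, so what signal over background limits was not measured. The depth of 3 arrays was 477, 543 and 710 of 804 spots.

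In what follows each number of passing probes has the reported number after it in parentheses, and the cause of a difference was not tested unless it is named. The tool was limma except in the unmoderated fits. With no dye coefficient the number in cecal tonsil cells was 0 (1) for PGN at 6 h. In spleen cells it was 5 (12) for PGN in the average, and 0 (1) for PGN at 6 h. With 1 fit per tissue the number in cecal tonsil cells was 14 (5) for PGN and 1 (0) for CE in the average, and 0 (1) for DNA at 6 h, 15 (3) for PGN at 12 h and 3 (10) for CE at 3 h. It was also 2 (0) for PGN in the change with time, and 2 (0) for PGN minus DNA and 2 (0) for CE minus PGN. Spleen cells had 0 (12) for PGN and 0 (6) for CE in the average, 0 (1) for DNA at 3 h and 0 (1) for PGN at 6 h, and 0 (6) for PGN and 1 (15) for CE in the change with time.

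Replicate numbers were not taken to pair the arrays, and the block on them is given as 1 more alternative. Residuals of same-numbered arrays of 2 components in a tissue and time had a mean rho of 0.0538, with 29 of 72 pairs over 0.1. With another number and the same dye orientation the mean was -0.00618. A weak pairing was thus not excluded. With a replicate block in place of the dye coefficient the number in cecal tonsil cells was 0 (1) for PGN at 6 h and 2 (0) for CE at 12 h, and 1 (0) for DNA in the change with time. For spleen cells it was 0 (1) for DNA at 3 h. A random block of tissue, time and replicate number had a consensus correlation of 0.0506 and moved no count by over 1.5 times.

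With arrays centred on the median the number in cecal tonsil cells was 1 (0) for DNA in the change with time. With arrays centred and scaled the number in cecal tonsil cells was 3 (0) for DNA and 3 (5) for PGN in the average, and 51 (0) for DNA at 3 h, 0 (1) for DNA at 6 h, 2 (1) for PGN at 6 h, 1 (3) for PGN at 12 h and 3 (10) for CE at 3 h. There were also 14 (0) for DNA in the change with time, and 3 (0) for PGN minus DNA. The spleen had 5 (12) for PGN and 1 (6) for CE in the average, 5 (17) for PGN at 12 h, 3 (0) for CE at 3 h and 17 (27) for CE at 6 h, and 0 (6) for PGN and 8 (15) for CE in the change with time. Between the tissues it was 0 (6) for PGN. Over probes with a value on all 72 arrays the number in cecal tonsil cells was 0 (1) for PGN at 6 h and 5 (10) for CE at 3 h, and 1 (0) for DNA in the change with time. In the spleen it was 0 (1) for DNA at 3 h. The tissues differed at 11 (6) for PGN.

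With array weights the number in cecal tonsil cells was 13 (5) for PGN in the average, and 0 (1) for DNA at 6 h, 2 (0) for DNA at 12 h, 8 (1) for PGN at 6 h, 1 (10) for CE at 3 h and 1 (0) for CE at 12 h. Further, it was 1 (0) for DNA and 1 (0) for PGN in the change with time, and 2 (0) for PGN minus DNA and 3 (0) for CE minus PGN. In spleen cells it was 21 (12) for PGN and 11 (6) for CE in the average, and 0 (1) for DNA at 3 h, 8 (1) for PGN at 6 h, 2 (0) for CE at 3 h and 44 (27) for CE at 6 h. Beside these it was 1 (6) for PGN and 29 (15) for CE in the change with time. For the tissues it was 16 (6) for PGN and 2 (0) for CE. With these weights 0 (1) gene lists passed. With no averaging of spots the number in cecal tonsil cells was 8 (5) for PGN and 1 (0) for CE in the average, and 1 (0) for PGN at 3 h, 0 (1) for PGN at 6 h, 16 (3) for PGN at 12 h, 5 (10) for CE at 3 h and 1 (0) for CE at 6 h. It was also 2 (0) for CE in the change with time, and 3 (0) for PGN minus DNA and 1 (0) for CE minus PGN. Spleen cells had 5 (12) for PGN and 1 (6) for CE in the average, and 0 (1) for DNA at 3 h, 7 (0) for DNA at 12 h, 0 (1) for PGN at 6 h, 84 (17) for PGN at 12 h and 6 (0) for CE at 12 h. There were also 1 (6) for PGN in the change with time. Between the tissues it was 3 (6) for PGN.

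At the unadjusted p of an unmoderated fit per tissue the number in cecal tonsil cells was 20 (0) for DNA, 34 (5) for PGN and 16 (0) for CE in the average, and 15 (0) for DNA at 3 h, 20 (1) for DNA at 6 h, 16 (0) for DNA at 12 h, 7 (0) for PGN at 3 h, 12 (1) for PGN at 6 h, 42 (3) for PGN at 12 h, 22 (10) for CE at 3 h, 10 (0) for CE at 6 h and 20 (0) for CE at 12 h. Further, it was 12 (0) for DNA, 18 (0) for PGN and 16 (0) for CE in the change with time, and 34 (0) for PGN minus DNA, 11 (0) for CE minus DNA and 28 (0) for CE minus PGN. For spleen cells it was 4 (0) for DNA, 24 (12) for PGN and 31 (6) for CE in the average, and 7 (1) for DNA at 3 h, 3 (0) for DNA at 6 h, 18 (0) for DNA at 12 h, 5 (0) for PGN at 3 h, 2 (1) for PGN at 6 h, 48 (17) for PGN at 12 h, 13 (0) for CE at 3 h and 13 (0) for CE at 12 h. Beside these it was 6 (0) for DNA, 15 (6) for PGN and 30 (15) for CE in the change with time, and 5 (0) for PGN minus DNA, 22 (0) for CE minus DNA and 7 (0) for CE minus PGN. The lists numbered 4 (1). With adjusted p of that unmoderated fit the number in cecal tonsil cells was 15 (5) for PGN and 1 (0) for CE in the average, and 0 (1) for DNA at 6 h, 17 (3) for PGN at 12 h and 0 (10) for CE at 3 h. It was also 2 (0) for PGN in the change with time, and 2 (0) for PGN minus DNA and 2 (0) for CE minus PGN. The spleen had 0 (12) for PGN and 0 (6) for CE in the average, 0 (1) for DNA at 3 h and 0 (1) for PGN at 6 h, and 0 (6) for PGN and 2 (15) for CE in the change with time.

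With the median over spots the number in cecal tonsil cells was 0 (1) for DNA at 6 h and 5 (3) for PGN at 12 h, and 2 (0) for PGN minus DNA. With the repeated value of an array as missing the number in cecal tonsil cells was 2 (0) for DNA in the average, and 4 (0) for DNA at 3 h, 0 (1) for DNA at 6 h, 0 (1) for PGN at 6 h and 4 (10) for CE at 3 h. In the spleen it was 14 (6) for CE in the average, 30 (17) for PGN at 12 h and 2 (0) for CE at 12 h, and 1 (0) for DNA in the change with time. With unnamed spots averaged by layout position the number in cecal tonsil cells was 0 (1) for PGN at 6 h, and 1 (0) for DNA and 3 (0) for CE in the change with time. In spleen cells it was 2 (1) for DNA at 3 h, 0 (1) for PGN at 6 h and 14 (27) for CE at 6 h, and 7 (15) for CE in the change with time. The tissues differed at 2 (6) for PGN. With named genes only the number in cecal tonsil cells was 0 (1) for PGN at 6 h, 4 (0) for CE in the change with time, and 1 (0) for PGN minus DNA. Spleen cells had 7 (12) for PGN and 2 (6) for CE in the average, 2 (1) for DNA at 3 h, 0 (1) for PGN at 6 h and 12 (27) for CE at 6 h, and 3 (6) for PGN and 5 (15) for CE in the change with time. For the tissues it was 0 (6) for PGN. Averaging by position and testing named genes only leave fewer probes to count.

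Without the 3 arrays with missing spots the number in cecal tonsil cells was 0 (10) for CE at 3 h and 1 (0) for CE at 12 h, and 1 (0) for DNA in the change with time. For spleen cells it was 0 (1) for DNA at 3 h. TOB1 in cecal tonsil CE at 3 h turned from -1.44 to 0.0491. Without the 5 doubted arrays the number in cecal tonsil cells was 2 (1) for PGN at 6 h, 8 (3) for PGN at 12 h, 0 (10) for CE at 3 h and 1 (0) for CE at 12 h, 1 (0) for PGN in the change with time, and 1 (0) for PGN minus DNA and 1 (0) for CE minus PGN. The spleen had 22 (12) for PGN and 15 (6) for CE in the average, and 0 (1) for DNA at 3 h, 11 (1) for PGN at 6 h and 10 (17) for PGN at 12 h. There were also 0 (6) for PGN in the change with time, and 10 (0) for PGN minus DNA and 1 (0) for CE minus DNA. Between the tissues it was 14 (6) for PGN and 3 (0) for CE. TOB1 at 3 h turned to 0.0451, and 0 (1) gene lists passed. The 5 arrays were chosen after their values were seen, so higher counts can follow from that choice. With spleen PGN 6 h replicate 2 turned the number in spleen cells was 12 (6) for CE in the average, 14 (1) for PGN at 6 h, and 9 (0) for PGN minus DNA and 1 (0) for CE minus DNA. The tissues differed at 18 (6) for PGN and 3 (0) for CE. The turned array was picked because it lay opposite to its group, so more passing probes for PGN follow from that choice. The CE arrays were not turned, but all groups share 1 estimate of the spread per probe, which the turned array enters. How far this accounts for the higher counts for CE was not tested.

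With each array left out in turn the number in cecal tonsil cells was 0 to 1 for DNA, 1 to 6 for PGN and 0 to 2 for CE in the average, and 1 to 3 for DNA at 6 h, 0 to 1 for DNA at 12 h, 0 to 1 for PGN at 6 h, 0 to 11 for CE at 3 h, 0 to 3 for CE at 6 h and 0 to 4 for CE at 12 h. Further, it was 0 to 2 for DNA, 0 to 1 for PGN and 0 to 6 for CE in the change with time, and 0 to 1 for CE minus DNA. In the spleen it was 0 to 17 for PGN and 0 to 14 for CE in the average, and 0 to 2 for DNA at 3 h, 0 to 10 for PGN at 6 h, 3 to 28 for PGN at 12 h and 0 to 1 for CE at 12 h. Beside these it was 0 to 1 for DNA, 0 to 11 for PGN and 4 to 17 for CE in the change with time, and 0 to 8 for PGN minus DNA and 0 to 1 for CE minus DNA. For the tissues it was 3 to 12 for PGN and 0 to 1 for CE. The gene lists ranged from 0 to 1. TOB1 in cecal tonsil CE at 3 h ranged from -1.99 to 0.0526. In spleen CE at 6 h spot_153 ranged from -1.53 to 0.000637 and spot_154 from -1.52 to 0.0191. Over the 89 pairs that passed, 513 of 752 values with an array left out kept side and direction, 236 missed the threshold and 3 reversed, and 20 pairs passed with any 1 array left out. Of the pairs that had not passed, 312 of 324 values stayed so and 12 passed.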

Other observations

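The averages of unnamed spots by layout position, and their fits with 1 array left out, were chosen only after the data were seen. The annotation names no gene at 21 layout positions, and some of them moved with the cell envelope and PGN in spleen cells. Position 219 rose 8.62-fold with the cell envelope at 6 h (2.15 ± 0.38, n = 4, higher in 4 of 4 arrays, limma adjusted p = 1.98e-05) and 4.00-fold with PGN at 12 h (1.39 ± 0.38, 4 of 4, 0.00716). Over the times it rose with PGN (0.93 ± 0.22, n = 12, 11 of 12, 0.0108) and with the cell envelope (0.74 ± 0.22, 10 of 12, 0.0318). In cecal tonsil cells with PGN at 12 h it was at -0.82 (lower in 4 of 4, 0.363). Position 41 rose 3.26-fold with the cell envelope at 6 h (1.18 ± 0.22, 4 of 4, 3.63e-05), in its average (0.50 ± 0.13, 8 of 12, 0.0195) and with PGN at 12 h (0.68 ± 0.22, 4 of 4, 0.0303). Position 207 stood 2.35-fold higher with PGN at 12 h (0.86 ± 0.17, 4 of 4, 0.000244). Position 247 fell in the cell envelope average (-0.44 ± 0.12, lower in 8 of 12, 0.0261). With the cell envelope at 6 h positions 219 and 41 passed with any 1 array left out. With PGN at 12 h none of the 3 positions passed without replicate 3, the array with ACTB at 2.46: position 219 was at 1.06 (0.167), position 207, at 2.57 on that array, at 0.27 (0.167) and position 41 at 0.76 (0.0639). Position 41 there also missed the threshold without replicate 1 (0.137) or 2 (0.157). In the averages the threshold was missed without any 1 of 3 of the 12 arrays for position 219 with PGN, and with the cell envelope without any 1 of 9 for position 219, 3 for position 41 and 6 for position 247.

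The T cell cytokines IL2 and IFNG did not pass in an averaged response. In cecal tonsil cells with the cell envelope IL2 was at 0.40 ± 0.21 (higher in 8 of 12 arrays, adjusted p = 0.663) and IFNG at 0.43 ± 0.27 (7 of 12, 0.785). In spleen cells with PGN, where IL2RA rose, IL2 was at -0.09 ± 0.21 (6 of 12, 0.884) and IFNG at -0.17 ± 0.27 (3 of 12, 0.848).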
